A study of Mus musculus with 3 samples.

How the data were processed

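Gastrocnemius RNA from transgenic mice was measured on 3 Affymetrix Mouse 430 2.0 arrays, which carry short oligonucleotide probes grouped into probe sets. Per the labels, the mice carry Akt, a kinase of the insulin and IGF1 pathway, joined to an oestrogen-binding domain and made in skeletal muscle alone. Tamoxifen is said there to stabilise this fusion, after which the muscle grows. The groups were oil for 24 h, tamoxifen for 24 h and tamoxifen for 48 h, with 1 array each, and every array held RNA pooled from 3 to 4 mice. Per the labels, the strain was C57BL/CD1, and total RNA was purified with Trizol and RNeasy columns and labelled with biotin by the standard Affymetrix protocol.

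The deposited values were intensities on a linear scale, 1 per probe set and array, made by the authors from the scanned arrays. The method of summary, background correction and scaling was not given in the sources used here, and no detection calls were used. The deposited medians over all probe sets were 15.2 on the oil array, 13.2 on the tamoxifen 24 h array and 13.8 on the tamoxifen 48 h array, and the deposited maxima were 11304, 11388 and 10578. All 3 columns of the table were used.

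Of 45101 probe sets, 64 manufacturer's controls were set aside. The platform annotation gave 1 gene to 34945 of the others and several genes to 932, and 9160 were not listed in it; symbols were updated through Entrez identifiers to the RefSeq gene table of GRCm38.p6. No gene was named from a probe set with several genes. A probe set was kept when its percentile rank, averaged over the 3 arrays, was 0.5 or more, which left 21804 probe sets, 19362 of them with 1 gene. The arrays were scaled to the same median over the kept probe sets, by factors of 1.01 for oil, 0.944 for tamoxifen 24 h and 1.05 for tamoxifen 48 h. A floor of 4.05, the 25th percentile of all scaled values, was then set, and log2 values were taken. A ratio with one side at the floor is a lower bound and is written as at least N-fold. Each gene was represented by its kept probe set of highest mean rank, which gave 11092 genes, 5001 of them with 2 or more kept probe sets.

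With 1 array per group there is no replicate error, and the number of arrays limits the precision. No statistical test between groups was made and no p-value is given; the words higher and lower for a single gene refer to a size rule of 2-fold or more. The spread of log2 ratios between probe sets of the same gene served as a technical yardstick. It does not measure variation between mice or arrays. No 48 h vehicle array was analysed, so time and treatment are not separated at 48 h. No tamoxifen array from mice without the fusion was included, so other effects of tamoxifen are not separated from those of Akt.

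Before the data were examined, 32 gene lists were written from general knowledge, and so was the rule for naming genes. For each list with at least 5 members compared, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these arrays and is not a test. Values below percentile 2.5 or above 97.5 are called outside the central range. Some members belong to more than 1 list; of 20 glucocorticoid-responsive genes compared, 8 also stood in a FoxO list. The naming rule took the 12 highest and 12 lowest genes of each comparison with oil and 8 of each for tamoxifen 48 h against 24 h. Such genes had to be at least 2-fold different with the same sign in all kept probe sets, and clone or predicted names were not used. The rule also took up to 4 members of each list by size of change and a fixed set that included Akt1, Akt2, Smad2, Smad3, Esr1, Foxo1, Foxo3 and Igf1. Other members that complete a small count were named after their values had been seen. Mstn and Rps6kb1 had no probe set of their own in the annotation used and were not analysed here.

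Both comparisons with oil share the oil array. Their correlation and overlap were therefore set beside 100 simulations of 3 unchanged arrays and beside the overlap of independent lists. The simulated noise was the standard deviation of the tamoxifen 48 h to 24 h log2 ratios in each of 20 expression bins, divided by the square root of the number of arrays compared. It includes any real difference between those arrays. It does not cover an oil array noisier than the tamoxifen arrays, which would raise the correlation and the overlap as well.

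The calculation was tested on simulated data with 200 changed genes per tamoxifen array and the same kind of noise. In the simulated comparison of tamoxifen 24 h with oil, which held 11033 genes, the 2-fold rule found 95.7% of genes changed 4-fold, 89.6% of those changed 3-fold, 50% of those changed 2-fold and 10% of those changed 1.5-fold. It also called 440 of 10842 unchanged genes. Of 200 simulated lists of 20 genes with no shift, 7 fell outside the central range, and 153 of 200 did so when 0.3 was added to their medians. These lists were drawn at random with independent noise, so a small share outside was built in. Lists of genes that vary together were not simulated.

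Alternatives fixed beforehand were the deposited values with no scaling, quantile normalization, a loess curve on intensity with a span of 0.3, rank filters of 0.25 and 0.75 and no filter, no floor, a pseudocount in place of the floor, the mean over all kept probe sets of a gene, and the removal of probe sets whose names end in _x_at or _s_at. Counts were also taken at 1.5-fold and 3-fold, and over genes with 2 or more kept probe sets that all passed 2-fold. A floor at the 50th percentile and the count of genes for which 1 array stood apart were chosen after seeing the data. The alternatives used 1000 random lists each. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.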

Results

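Gene expression in gastrocnemius, a mostly fast-twitch muscle of the calf, was compared between mice given tamoxifen for 24 h or 48 h and mice given oil for 24 h. Per the labels, all mice carried a muscle form of Akt that tamoxifen stabilises. The genotype label reads Akt_Cre transgenic, and whether a Cre recombinase was also involved is not given in the sources used here. Each group was 1 array of RNA pooled from 3 to 4 mice, so no value below has a replicate error. On log2 values of the kept probe sets, the oil array correlated at r = 0.955 with the tamoxifen 24 h array and 0.954 with the tamoxifen 48 h array, and both tamoxifen arrays correlated at 0.966. Intensities below are scaled values and ratios are against oil unless stated. Each gene is read on its brightest probe set. Of 624 list genes within 2-fold of oil at 24 h, 315 had other kept probe sets, past 2-fold in 32 of these. At 48 h, 308 of 605 such genes had other kept probe sets, past 2-fold in 25.

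Akt1 read 100.2 on the oil array, 132.9 at 24 h and 111.8 at 48 h, and Akt2 read 220.2, 279.8 and 230.7. It was not examined whether these probe sets detect the transgene, and per the labels tamoxifen acts on the fusion protein, so they do not check the treatment. Esr1, which encodes oestrogen receptor alpha, read 225.0, 255.7 and 250.9. Among 27 PI3K, Akt and mTOR pathway genes, none was 2-fold different at 24 h and 1 was at 48 h: Ddit4, an inhibitor of mTOR complex 1, was 2.20-fold lower. Other kept probe sets reached log2 ratios of -2.39 for Gsk3b and -1.49 for Deptor at 24 h. The list medians were -0.02 at 24 h and -0.03 at 48 h, at percentiles 12.5 and 23.5 of the random lists.

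The first comparison asked what 24 h of tamoxifen does against time-matched oil. Fbxo32 (atrogin-1), a muscle ubiquitin ligase, read 490 on oil and 93.3 at 24 h, 5.25-fold lower, with its 3 kept probe sets in the same direction, and Trim63 (MuRF1), another, read 2111 on oil and 744 at 24 h, 2.84-fold lower. The highest ratios belonged to Flrt1, an adhesion protein (10.5-fold), Efr3b (9.75-fold), Sema3f, a secreted guidance factor (7.69-fold), Lcn2 (lipocalin 2, 7.26-fold), Mybph, a myosin-binding protein (7.23-fold), and Pttg1 (securin, 6.81-fold). Zfp385a and the protease Corin were at the floor on the oil array and were at least 8.82-fold and at least 7.70-fold higher. Gdpd3 (10.1-fold), Lfng (6.56-fold), Aars2 (6.15-fold) and Max (5.59-fold) completed the 12 highest. Sarcolipin, encoded by Sln, an inhibitor of the sarcoplasmic calcium pump, was 4.03-fold higher. The other lowest genes included Klf12 (5.83-fold lower, with another kept probe set at a log2 ratio of -0.08), Crim1 (4.70-fold), Chac1 (4.68-fold), Dhdh (4.72-fold), Gas2l3 (4.37-fold, with another kept probe set at -0.60 in log2) and Zbed6 (4.20-fold). Serpinb6e was 7.47-fold lower, and Trpm2, Amelx, Nwd1 and Thoc2l were lower by 4.08-fold to 4.45-fold.

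In all, 261 genes were at least 2-fold higher and 275 at least 2-fold lower at 24 h, of 11092. In simulated data with the noise of the tamoxifen arrays, 440 of 10842 unchanged genes passed the same rule, so a gene cannot be taken as changed on that size alone. Between the tamoxifen arrays themselves fewer passed, 200 higher and 157 lower of 11092, so 440 does not estimate the number of false calls. Higher genes made up 48.7% of the calls, against 63.8% with the deposited values unscaled and 60.0% after quantile normalization. Without scaling, the median ratio of all genes was 0.13 instead of 0.04. The share was 36.8% with a filter at rank 0.25, where 640 genes were higher and 1097 lower, and 63.2% at rank 0.75, where 115 were higher and 67 lower. Of 172 called genes with a second kept probe set, 127 had it in the same direction (73.8%, against 61.1% of all such genes), and 39 had it past 2-fold as well. Of the 12 genes named as higher, 10 were also at least 2-fold higher at 48 h. Both ratios share the oil array, so a low oil reading alone could place a gene in both. Of the 12 named as lower, 9 were within 2-fold of oil at 48 h and 11 (all but Fbxo32) were at least 2-fold below both other arrays at 24 h. With the floor raised to the 50th percentile, this no longer held for Serpinb6e, Trpm2, Amelx and Thoc2l. The log2 ratios at 24 h were then 1.19 for Lfng, 1.15 for Corin, 1.34 for Zfp385a, 1.84 for Aars2 and 1.97 for Max. Of the kept probe sets without a gene of their own, 144 were likewise 2-fold below both other arrays at 24 h.

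The second comparison set 48 h of tamoxifen against the 24 h oil array. Flrt1 reached 17.98-fold, Mybph 16.6-fold (259 to 4296), Corin at least 14.97-fold and Atp1b4, a muscle protein of the sodium pump family, 11.9-fold. Tnfrsf12a, the receptor for TWEAK, was 11.1-fold higher, from 130.4 on oil to 300.4 at 24 h and 1445 at 48 h. Zfp385a was at least 10.6-fold higher. Efr3b (9.26-fold), Ddc (9.20-fold), Ccdc141 (8.20-fold, with another kept probe set at a log2 ratio of 0.46), the nicotinamide riboside kinase Nmrk2 (8.14-fold), Lfng (7.64-fold) and Aars2 (7.05-fold) followed. Fbxo32 read 75.8 (6.46-fold lower). Tmem232 (18.3-fold), the peptide transporter Slc15a2 (7.43-fold), Eml2 (5.88-fold), Fhl3 (5.77-fold), Art5 (5.76-fold), Cilp2 (5.42-fold) and Pfkfb3, an enzyme that drives glycolysis through fructose 2,6-bisphosphate (5.29-fold), were also among the lowest, with Hs3st2 (4.96-fold), Lrrc2 (4.47-fold) and Htra4 (4.42-fold). Gdpd3, 10.1-fold higher at 24 h, was at the floor at 48 h. Some of these folds rest on a low reading near the floor. With the raised floor, log2 ratios at 48 h were 2.11 for Corin, 1.60 for Zfp385a and 2.26 for Ddc. They were 2.04 for Aars2, 1.91 for Ccdc141 and 1.41 for Lfng. Among the lower genes they were -2.90 for Tmem232, -1.41 for Eml2, -1.99 for Fhl3, -1.61 for Hs3st2 and -1.62 for Htra4. Gdpd3 was then at -0.40.

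At 48 h, 413 genes were at least 2-fold higher and 301 at least 2-fold lower, and 57.8% of the calls were higher, against 47.3% with no filter and 68.3% at rank 0.75. Probe sets of one gene went together more often here than at 24 h: 196 of 223 called genes had the second probe set in the same direction (87.9%, against 66.8% of all such genes), and 94 had it past 2-fold.

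**Figure D1:**
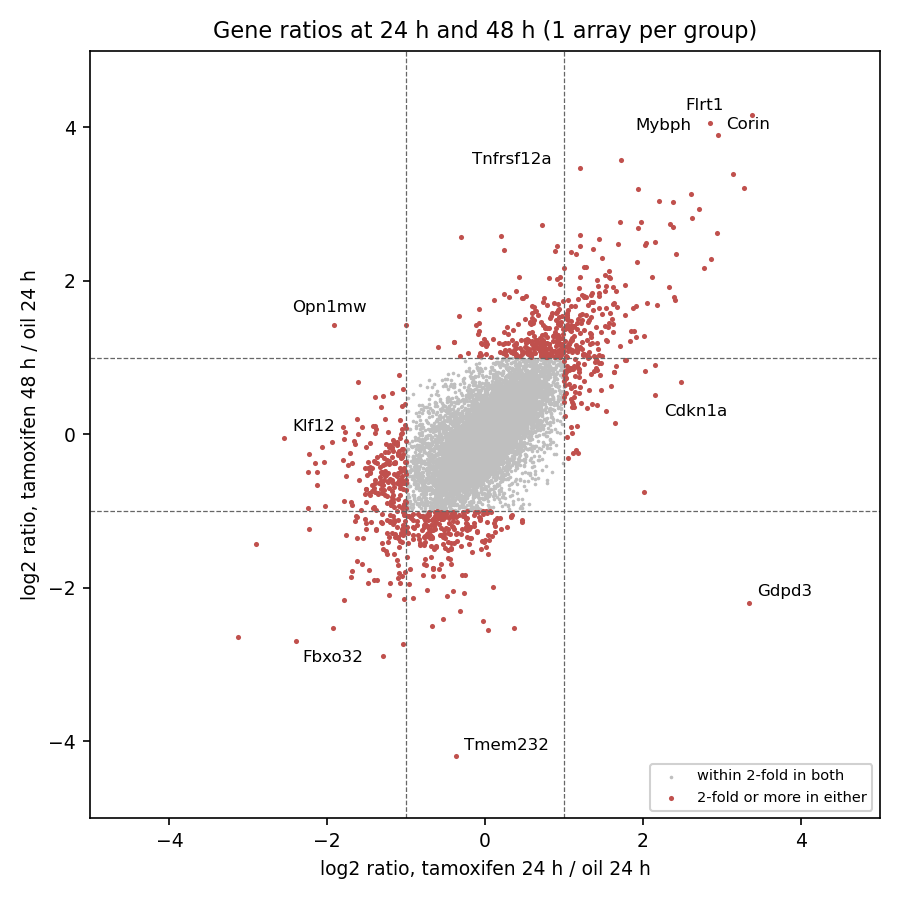
Log2 ratios of 11092 genes against the same oil array, with tamoxifen 24 h on the x axis and tamoxifen 48 h on the y axis; each point is 1 gene, red points are at least 2-fold different in either comparison and dashed lines mark 2-fold. Flrt1 and Mybph lie far up in both, Fbxo32 low in both, and Gdpd3 is high at 24 h and low at 48 h.

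Ratios at 24 h and 48 h went together across genes, with r = 0.686 and a covariance of 0.188. Unchanged arrays that share a control gave r = 0.50 and a covariance of 0.087 on average in simulation. Genes higher in both numbered 176, against 29.2 simulated and 9.72 for independent lists; genes lower in both numbered 80, against 29.0 and 7.46. Genes are not independent replicates. The single oil array enters both ratios, so an oil array noisier than simulated would raise these figures too and was not separated from a shared response. The oil array stood at least 2-fold above both others in 80 genes and below both in 176. By definition these are the same genes as those lower and higher in both comparisons. The 24 h array stood above in 16 and below in 72, and the 48 h array above in 64 and below in 79. These counts depended on scaling and the filter: in the same order they were 65 and 208, 24 and 38, and 39 and 121 unscaled, 28 and 87, 2 and 15, and 26 and 14 at rank 0.75, and 374 and 337, 137 and 376, and 299 and 289 at rank 0.25.

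The third comparison set tamoxifen 48 h against 24 h. Tnfrsf12a (4.81-fold), Trib3, a pseudokinase that binds Akt (4.48-fold), Angptl4, an inhibitor of lipoprotein lipase (4.01-fold), and Tceal7 (5.21-fold) were higher. Opn1mw (10.2-fold), Rpgrip1 (7.39-fold), Klf12 (5.66-fold, with another kept probe set at a log2 ratio of 0.22) and Taf15 (4.87-fold) were higher as well. Opn1mw, Klf12 and Taf15 had been more than 3-fold below oil at 24 h (Taf15 at a log2 ratio of -0.40 with the raised floor). Gdpd3 was at least 46.3-fold lower. Tmem232 (14.2-fold), Fhl3 (7.41-fold), Sln (6.81-fold), Eml2 (6.05-fold), Cilp2 (5.31-fold), Baiap2l1 (4.23-fold, with another kept probe set at a log2 ratio of -0.49) and Hs3st2 (3.97-fold) were lower. With the raised floor, log2 ratios were -3.73 for Gdpd3, -2.53 for Tmem232 and -2.35 for Fhl3. They were -1.45 for Eml2, -1.29 for Hs3st2 and -1.06 for Baiap2l1. In all, 200 genes were higher and 157 lower, and the balance depended on scaling. Higher genes made up 56.0% of the calls, against 29.3% unscaled, where the median ratio of all genes was -0.18, 42.7% after quantile normalization and 47.2% after loess. Of 80 called genes with a second kept probe set, 49 had it in the same direction (61.3%, against 57.5% of all such genes).

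Genes under FoxO control, which Akt restrains, went in both directions. Among 22 ubiquitin ligase and FoxO atrophy genes, Fbxo32 and Trim63 were lower at 24 h and Cdkn1a, encoding the cell cycle inhibitor p21, was higher (148.0 to 660.5, 4.46-fold). At 48 h only Fbxo32 passed 2-fold; Trim63 was at 1149, and Cdkn1a was at 210.7. The list medians were -0.0020 and -0.05 (percentiles 15.5 and 13.9). Foxo1 read 157.2, 228.5 and 153.8, and Foxo3 134.2, 96.7 and 98.4. Of 18 insulin- and FoxO-responsive metabolic genes, 4 were lower at 24 h: Ccng2 (2.79-fold), Klf15 (2.02-fold), Pdk4, which restrains pyruvate oxidation, at 430 against 1010, and Pik3ip1, an inhibitor of PI3K, at 125 against 278. At 48 h Ccng2 (3.84-fold), Klf15 (3.46-fold), Depp1 (2.90-fold) and Pik3ip1 (2.17-fold) were lower and Angptl4 was 6.62-fold higher, while Pdk4 was back at 1029. This list's median was -0.10 at 24 h (percentile 3.07) and -0.28 at 48 h (percentile 0.22, outside the central range under all 11 alternatives).

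Of 26 autophagy and mitophagy genes, 1 passed 2-fold, Gabarapl1 at 48 h (2.11-fold lower). Another kept probe set of Rb1cc1 read -1.71 at 24 h and -1.21 at 48 h in log2, while Bnip3 read 2396, 1661 and 1234 and Map1lc3b 2324, 1530 and 1223. The list medians were -0.02 at 24 h (percentile 10.5) and -0.16 at 48 h (percentile 1.29, outside the central range under 10 of 11 alternatives). None of 30 proteasome subunits was 2-fold different, with medians of 0.21 and 0.15 (percentiles 95.7 and 84.5).

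Myostatin and Smad signalling restrains muscle growth, and the series is titled for Smad2 and Smad3. Smad2 read 68.4 on oil, 88.3 at 24 h and 96.1 at 48 h, and Smad3 333, 397 and 365, all within 2-fold. Other kept probe sets went the other way at 24 h, at log2 ratios of -0.77 for Smad2 and -0.69 for Smad3. Of 40 pathway genes, 1 passed 2-fold at 24 h (Inhbb, an activin subunit, 2.25-fold lower, with its other kept probe set at a log2 ratio of 0.48) and 3 at 48 h: Bmp2 (2.22-fold lower), the myostatin receptor Acvr2b (2.19-fold lower, with its other kept probe set at a log2 ratio of -3.12 at 24 h) and Tgfb1 (2.05-fold higher). The medians of -0.05 and -0.09 lay at percentiles 7.63 and 10.3. Igf1 read 682, 645 and 586.

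**Figure D2:**
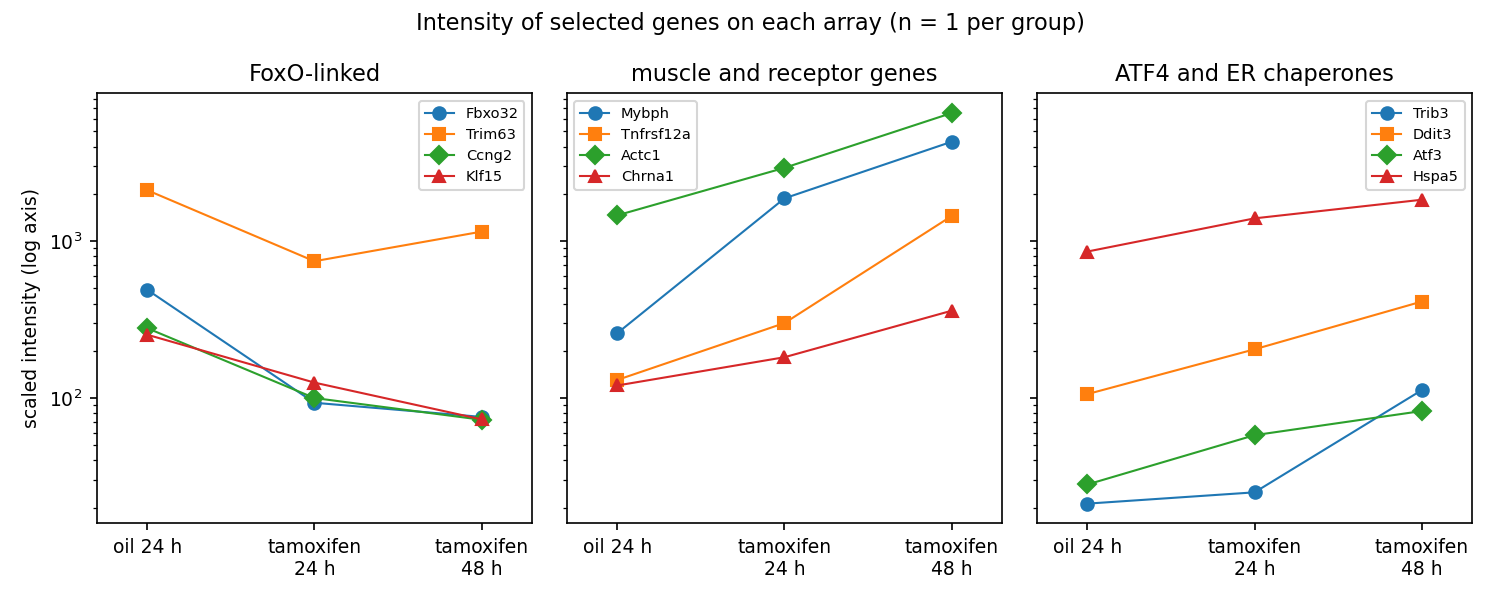
Scaled intensity on a log axis for 12 genes on the 3 arrays (x axis: oil 24 h, tamoxifen 24 h, tamoxifen 48 h; n = 1 array each, lines join values of 1 gene). Fbxo32 goes from 490 to 75.8, Mybph goes from 259 to 4296 and Ddit3 from 105.9 to 411.8.

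Genes of the amino acid and ATF4 response and of the endoplasmic reticulum were higher as groups. Of 24 ATF4-linked genes, 4 were higher at 24 h (Atf5, Mthfd2, Slc7a5 and Atf3, the last 2.06-fold) and Chac1 was lower. At 48 h 6 were higher, led by Trib3 (21.2 to 112.3, 5.29-fold), the stress factor Ddit3 (3.89-fold) and Atf3 (2.94-fold). The other kept probe set of Ddit3 was within 2-fold at 48 h, at a log2 ratio of 0.78. The rest were Slc7a5, an amino acid transporter, Mthfd2 and Psat1, and no gene of the list was lower. Medians were 0.31 (percentile 99.5) and 0.37 (percentile 99.9), and each was inside the central range under 1 of 11 alternatives. Of 21 endoplasmic reticulum chaperone genes, 17 had ratios above 0 at 24 h and 19 at 48 h. The chaperone BiP, encoded by Hspa5, read 858, 1396 and 1834 (2.14-fold at 48 h, where its other probe sets ranged from 0.03 to 1.45 in log2). At 48 h Manf was 2.06-fold and Pdia4 2.28-fold higher. Pdia4 rested on 1 kept probe set of low intensity, 11.1 on oil and 25.4 at 48 h. Medians were 0.30 (percentile 99.2) and 0.55, above all 10000 random lists at 48 h.

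The ribosome lists were inside the central range. None of 37 ribosome biogenesis factors was 2-fold different at 24 h, Rrp12 was 2.08-fold higher at 48 h, and the kept probe sets of Polr1a ranged in log2 from -1.10 to 1.76 at 24 h and from -0.84 to 2.24 at 48 h. The medians were 0.13 and 0.11 (percentiles 83.1 and 86.2). Myc read 30.9, 17.9 and 33.1. Among 38 cytosolic ribosomal protein genes, the medians were 0.02 and -0.04 (percentiles 41.4 and 9.38); Rpl39 was 2.36-fold and 2.04-fold higher and Rps27 2.41-fold lower at 48 h, and neither exceeded an intensity of 95.6. In 18 heat shock and sarcomere chaperones the small chaperone Hspb8 was 2.03-fold and 2.62-fold higher, and Hspa1a and Hspa1b were 3.36-fold and 2.45-fold lower at 48 h. This list's medians, 0.17 and 0.09, lay at percentiles 91.3 and 73.7.

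Of 17 contractile genes of fast fibres, none passed 2-fold, and medians were -0.0046 and 0.01 (percentiles 22.5 and 37.4). Slow-fibre genes lay lower at 48 h, with a median of -0.16 against oil (percentile 2.08, outside the central range under 10 of 11 alternatives) and -0.34 against tamoxifen 24 h, below all 10000 random lists. Myh7, the slow myosin heavy chain, read 1041, 894 and 614, Tnnc1 1207, 1346 and 851 and Tpm3 1173, 1201 and 698, none past 2-fold, but the 5 kept probe sets of Tpm3 ranged in log2 from -0.92 to 0.54 at 48 h; Casq2 went the other way (2.52-fold higher at 48 h). Of 22 myogenic, embryonic and denervation genes, 4 were higher at 48 h: cardiac actin Actc1 (1459 to 6545, 4.49-fold), the satellite cell cadherin Cdh15 (3.46-fold), the acetylcholine receptor subunit Chrna1 (3.00-fold) and Myog, a myogenic transcription factor (2.02-fold). Actc1 and Cdh15 had passed 2-fold at 24 h, and the list medians of 0.08 and 0.07 were inside the central range (percentiles 69.0 and 72.2).

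Of 24 fatty acid uptake and oxidation genes, Plin5, a lipid droplet protein, was 2.25-fold higher at 24 h; at 48 h Ucp3, a mitochondrial carrier (3.11-fold), Plin5 (2.19-fold) and Fabp3, the muscle fatty acid carrier (2.02-fold), were higher. The medians were 0.12 (percentile 75.02) and 0.36 (percentile 99.96). Of 23 glycolysis and glycogen genes, Ppp1r3c, which targets a phosphatase to glycogen, was 2.00-fold higher at 24 h and Pfkfb3 was 5.29-fold lower at 48 h, with medians of 0.06 and 0.12 (percentiles 53.1 and 86.3). None of 43 oxidative phosphorylation subunits passed 2-fold (medians 0.03 and 0.02, percentiles 46.7 and 38.3). Among 25 cholesterol and fatty acid synthesis genes, Dhcr7 was 2.88-fold and 3.65-fold higher, and the medians were 0.10 and -0.0077 (percentiles 75.4 and 46.1).

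**Figure D3:**
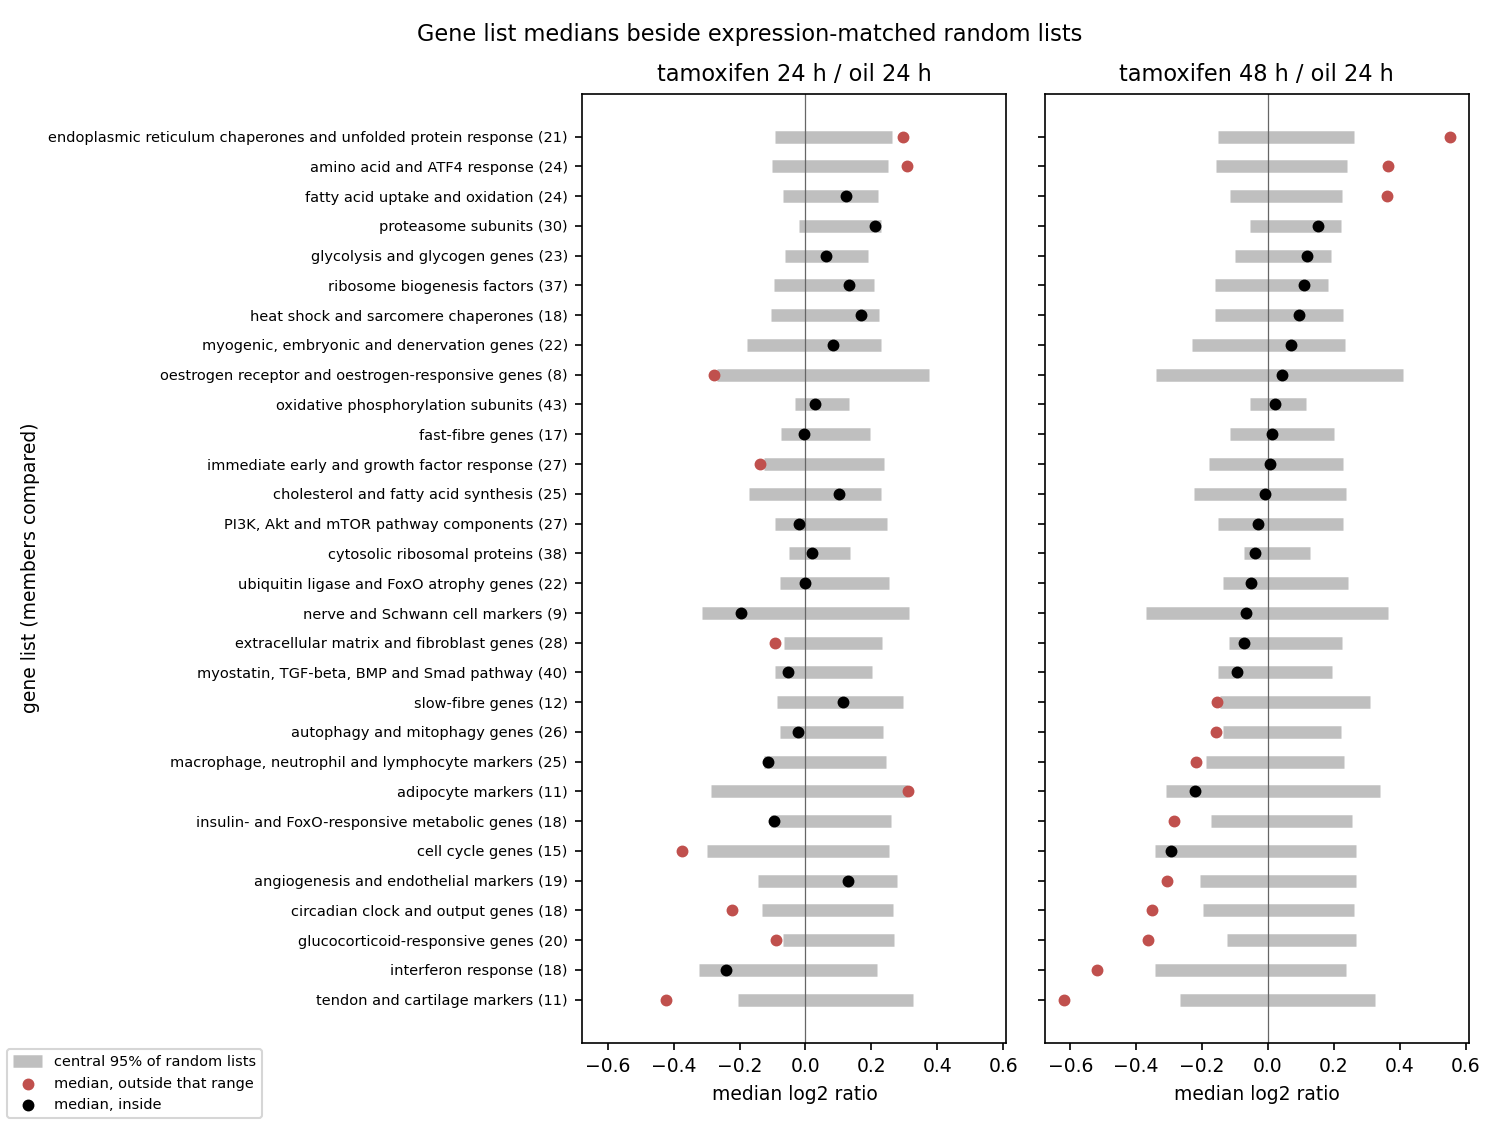
Median log2 ratio of 30 gene lists (y axis, with members compared) at 24 h on the left and 48 h on the right; points are medians, red where outside the central 95% of expression-matched random lists, which is drawn as a grey bar. Endoplasmic reticulum chaperones are at the top at 48 h (0.55) and tendon markers at the bottom (-0.62).

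Among 20 glucocorticoid-responsive genes, 5 were lower and 2 higher at 24 h, and 4 were lower and 1 higher at 48 h. Those lower were Fbxo32, Glul and Klf15 at both times, Trim63 and Pdk4 at 24 h and Ddit4 at 48 h, and those higher were Lcn2 at both times and Cdkn1a at 24 h. Glul, glutamine synthetase, read 2358, 1117 and 615, while Lcn2 was 7.26-fold and 4.85-fold higher. The medians were -0.09 at 24 h (percentile 1.20; 0.0044 with unscaled values) and -0.36 at 48 h (percentile 0.01). Circadian genes had medians of -0.22 and -0.35 (percentiles 0.38 and 0.13, 18 genes): Dbp was 2.05-fold and 2.01-fold lower and Rora 2.01-fold lower at 48 h, but Nr1d1 (2.68-fold) and Bhlhe41 (4.13-fold) were higher at 48 h. Hour of sampling was not given in the labels. Of 8 oestrogen-linked genes, Nrip1 was 2.49-fold lower at 24 h, with its 6 kept probe sets between -4.03 and 0.04 in log2, and Cyp1b1 2.44-fold lower at 48 h; medians were -0.28 (percentile 2.34, outside the central range under 4 of 11 alternatives) and 0.04 (percentile 48.3).

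Growth-related early genes were mixed. Of 27, Nr4a3 was 3.92-fold and 6.79-fold higher (log2 0.61 and 1.41 with the raised floor) and Egr1 3.41-fold higher at 48 h, whereas Smox (2.08-fold, then 3.59-fold) and Jund (2.09-fold at 24 h) were lower. Socs3 was 2.13-fold and 3.49-fold lower, but its 24 h log2 ratio was 0.092 without _x_at and _s_at probe sets, and another kept probe set read -0.0085 at 48 h. The medians were -0.14 at 24 h (percentile 1.85, outside the central range under 7 of 11 alternatives) and 0.0072 at 48 h (percentile 43.5). Of 15 cell cycle genes compared, 3 were lower at 24 h (Mcm4, 2.16-fold, Tk1, 2.13-fold, and Ccne2, 2.05-fold) and 2 at 48 h (Tpx2, 2.79-fold, and Ccne2, 2.44-fold). Mcm2 was 2.19-fold higher at 24 h, but its log2 ratio was -0.096 without _x_at and _s_at probe sets. Medians were -0.37 (percentile 0.68, outside the central range under 8 of 11 alternatives) and -0.29 (percentile 5.07).

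Of 11 tendon and cartilage genes, 9 had ratios below 0 at each time, with medians of -0.42 (percentile 0.05) and -0.62 (below all 10000 random lists). Tnmd read 560, 396 and 288, Clec3b was 2.85-fold and 2.35-fold lower, Cilp2 was 5.42-fold lower at 48 h, and Thbs4 read 810, 928 and 1550. Extracellular matrix and fibroblast genes (28) had medians of -0.09 (percentile 0.96; 0.0007 with unscaled values) and -0.07 (percentile 7.45), with Col12a1 2.02-fold lower at 24 h and Col1a1 2.26-fold higher at 48 h (another kept probe set, 0.13 in log2). Endothelial and angiogenesis genes (19) had medians of 0.13 (percentile 71.9) and -0.31 (percentile 0.37), none past 2-fold. Macrophage, neutrophil and lymphocyte markers (25) had medians of -0.11 (percentile 3.24) and -0.22 (percentile 1.32), and S100a9 (4.08-fold), S100a8 (3.24-fold) and Cd163 (2.10-fold) were lower at 48 h. Interferon-responsive genes (18) had medians of -0.24 (percentile 7.90) and -0.52 (percentile 0.10), with Gbp3 2.17-fold and 2.31-fold lower, Oas1a and Ifit3 2.09-fold and 2.06-fold lower at 24 h, and Ifit2 2.02-fold lower at 48 h. Adipocyte markers (11) had medians of 0.31 at 24 h (percentile 97.7, outside the central range under 8 of 10 alternatives) and -0.22 at 48 h (percentile 7.44); Pparg was 5.01-fold and 3.77-fold higher and Cidea 2.59-fold and 3.08-fold (log2 1.20 and 0.79, and 0.51 and 0.76, with the raised floor), Cidec was 2.15-fold higher at 24 h and Retn 2.04-fold lower at 48 h. Nerve and Schwann cell markers (9) had medians of -0.19 and -0.07 (percentiles 8.33 and 35.9), and Mag was 2.01-fold lower at 24 h. Only 3 blood and 3 epidermal genes were compared; Hbb-b2 was 2.47-fold lower at 24 h and Trp63 2.12-fold higher at 48 h.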

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

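In this part, the tests of 5' loss, of scaling and of whole-gene expression were chosen after the result had been seen, and the criterion for 5' loss was made stricter, and the 18S control added, once values were known. At 24 h and 48 h, 3 genes were at least 2-fold different from oil in opposite directions, and the difference between times was not tested. Both ratios share the oil array, which makes such genes few, so their number does not measure agreement between times. Gdpd3 had log2 ratios of 3.34 and at most -2.20, since it was at the floor at 48 h (at least 4.58-fold lower; -0.40 in log2 with the raised floor), Gm26782 of -1.003 and 1.42, and Opn1mw of -1.92 and 1.43, each from 1 kept probe set. Gm26782 lay outside the naming rule and was chosen after its values were seen.

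Among the manufacturer's control probe sets, which the comparisons did not use, the 3' transferrin receptor control was 2.96-fold and 3.35-fold above oil at 24 h and 48 h. The 3' pyruvate carboxylase control was 3.01-fold and 3.98-fold above oil. The genes' own probe sets, chosen after these values were seen, were higher too: Tfrc read 464, 1377 and 1917, and Pcx 114.0, 309.0 and 408. The 18 hybridisation spike probe sets had median log2 ratios of 0.07 and 0.06.

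Among kept probe sets without a gene of their own, 144 were at least 2-fold below both other arrays on the tamoxifen 24 h array, against 23 on the oil array and 18 on the 48 h array. Lower expression of whole genes was examined only on named genes that show the pattern, not on these 144 probe sets. Each low probe set was paired with every other kept probe set of its gene. In 9.24% of 714 such pairings the other was also 2-fold below both arrays, against 1.70% of all named kept probe sets. Pairings within a gene overlap, so no interval is given. Of 172 genes called at 24 h, 39 had a second probe set past 2-fold in the same direction, but those calls include this pattern. At 48 h it was 94 of 223 called genes. The low share of pairings argues against a 2-fold fall shared by all kept probe sets of these named genes. It cannot exclude a smaller fall of whole genes. The 144 low probe sets were not counted again after a loess correction, so a trend of scaling with intensity was not tested on them. Among all unnamed probe sets at 24 h against oil, the ratio of lower to higher was 8.39 (277 to 33). It was 3.44 (189 to 55) after a loess correction (Clopper-Pearson interval 2.53 to 4.73, which takes probe sets as independent). Such a trend therefore accounts for part of that wider excess at most. Loss of 5' sequence cannot be told apart: the log2 ratio of 5' to 3' signal at 24 h differed from the mean of the other arrays by -0.78 for pyruvate carboxylase, where those arrays were 0.31 apart, and by -0.90 for 18S ribosomal RNA, but by -0.05 to 0.13 for Gapdh, actin and transferrin receptor. Probe positions were not used here, so less intronic or nuclear RNA in that sample, and an effect of tamoxifen at 24 h, stay untested.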

How the results depend on the processing

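The floor at the 50th percentile, the count of genes for which 1 array stood apart and the list percentiles under the alternatives were chosen after seeing the data; all other alternatives were fixed before. No paired analysis was possible because each group is 1 array. The counts depended on the size rule, on the filter and on the need for every probe set to pass, by construction, and low signal over background limits what can be called. At 1.5-fold, higher and lower genes numbered 1061 and 1000 at 24 h, 1301 and 1188 at 48 h, and 767 and 648 for 48 h against 24 h, with 652 higher and 457 lower in both; at 3-fold they numbered 63 and 43, 113 and 58, and 37 and 20, with 40 and 7 in both. Where all of 2 or more kept probe sets had to pass 2-fold, the counts were 20 and 15, 48 and 23, and 6 and 5. A filter at rank 0.25 gave 640 and 1097, 925 and 989, and 867 and 576, with 337 and 374 in both. Rank 0.75 gave 115 and 67, 205 and 95, and 53 and 31, with 87 and 28. No filter gave 694 and 1237, 1011 and 1128, and 958 and 631, with 337 and 508. Unscaled values, where the median ratio of all genes was -0.18 instead of -0.02, gave 103 and 249 for 48 h against 24 h. A pseudocount, which makes ratios of values above the floor smaller, gave 129 and 92, with 51 lower in both. All other counts stayed within 1.5 times, and r between 24 h and 48 h ratios ranged with them from 0.610 to 0.744. Of 2133 values of named genes past 2-fold under the alternatives, 2034 moved by less than the spread between probe sets, 97 moved by more and 2 reversed: without _x_at and _s_at probe sets Mcm2 was at -0.096 and Socs3 at 0.092 at 24 h, through another probe set. The rank filters and no filter could not move a named value, because scaling and the probe set that stood for a gene stayed the same. Leaving out scaling shifted all genes of a comparison by less than that spread. Of 206 named values past 2-fold, 14 were no longer 2-fold with the raised floor and 27 with a pseudocount. Unscaled values lost 24, the mean of all kept probe sets 15, and loess and quantile normalization 12 each. Without _x_at and _s_at probe sets, 8 of 193 were lost. Of 984 list medians, 883 moved by less than the spread of random medians, and 3 reversed without scaling, which shifts all genes: fatty acid genes at 48 h against 24 h (-0.0098), glucocorticoid genes (0.0044) and extracellular matrix genes (0.0007) at 24 h. The counts of genes for which 1 array stood apart moved in 28 of 54 values. Of 31 list medians outside the central range, 19 stayed outside on the same side in every alternative run; the cell cycle list at 24 h reached percentile 43.1 and the insulin- and FoxO-responsive list at 48 h against 24 h 26.6.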

Other observations

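In this part, the tests on FoxO-linked genes were chosen after the result was seen, and the criterion for noise of single probe sets was changed more than once after its values were known; the test of neighbouring genes was chosen before. Between tamoxifen 24 h and 48 h, some runs of neighbouring related genes lay lower at 48 h, among them Cd209a (2.39-fold), Cd209b (2.28-fold), Cd209d (2.48-fold) and Cd209f (2.17-fold), which encode lectins, the interleukin 1 receptors Il1r1 (2.67-fold) and Il1r2 (2.71-fold), and S100a8 (2.20-fold) with S100a9 (2.46-fold). The genes of this paragraph were chosen after their values were seen. Adipocyte markers were also lower at 48 h than at 24 h, with a median of -0.41 (percentile 0.05), including Lipe (2.22-fold) and Retn (2.07-fold). Timp1, an inhibitor of matrix proteases, was 2.67-fold higher.

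Of 40 FoxO-linked genes, 5 were at least 2-fold lower at 48 h and 4 of them also at 24 h, which Akt activity could give. Angptl4 was 6.62-fold higher at 48 h and Cdkn1a 4.46-fold higher at 24 h. With 1 array per group and no tamoxifen array from mice without the fusion, Akt activity cannot be told apart from other effects of tamoxifen. Noise of single probe sets is argued against for the 4 genes with other kept probe sets. Of these, 5 of 5 (100%, Clopper-Pearson interval 47.8 to 100%) were lower by 1.5-fold or more, against 13.2% of all such probe sets. The interval takes the 5 probe sets as independent, though they come from 4 genes on the same arrays. Variation between arrays or pools is not covered. Agreement was common at 48 h, where 196 of 223 called genes had the second probe set in the same direction. Noise of a single probe set cannot be told apart for Klf15, the 1 gene with no other. Lower glucocorticoid action cannot be told apart, since the 12 glucocorticoid-responsive genes outside the FoxO lists had a median of -0.36 at 48 h (interquartile range -0.86 to -0.13) but -0.07 at 24 h (-0.27 to 0.44), when Fbxo32 was already 5.25-fold lower.

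A hypothesis for part of the calls is that pools of mice on a mixed background carried different haplotypes, which may move neighbouring genes together. Pairs of neighbouring genes called in the same direction numbered 39 at 48 h against oil, where 10000 shuffles gave 14 to 33 (central 95%), 23 at 24 h (6 to 20) and 14 for 48 h against 24 h (2 to 11). Pairs with unlike names numbered 36, 22 and 8, so the excess for 48 h against 24 h was lost without related neighbours. Both comparisons with oil share the oil array and several of the pairs, so their excesses are not separate results. Shared regulation of neighbours, as in the run of Chil1, Mybph, Myog and Ppfia4 higher at 48 h and chosen after their values were seen, would give such an excess too and was not separated from it.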
